A study of Homo sapiens with 16 samples.

How the data were processed

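Total RNA of 16 cultures of the human cancer cell lines H4, 42MGBA and HCT116 was hybridised to Affymetrix Human Gene 1.0 ST arrays, 1 array per culture, per the labels. The deposited table holds 33297 rows, 1 per probe set, and 16 columns of log2 expression values; the authors made them with Affymetrix Expression Console and RMA per the submitters' processing notes, with versions and settings not given in the sources used here. That the values are log2 follows from their range. RMA corrects background, puts the arrays it is given on a common distribution and summarises probes into 1 value per probe set. Array medians were at least 6.23 in H4 and 6.24 in HCT116 and at most 5.05 in 42MGBA, and the mean interquartile range was 3.60, 3.57 and 3.18, so the 42MGBA arrays are on another scale. Levels are therefore not compared between 42MGBA and the other lines, and their narrower range bears on the size of differences within 42MGBA. The genome build of the array annotation was not named, so no coordinates are given. For arrays the number of samples limits the precision; detection calls over background were not used here and not all levels under an array's lower quartile are named.

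Samples were grouped from their titles into H4 deficient (parental, clones 10 and 12), H4 corrected (8-1, 8-3, 88-1), 42MGBA deficient (parental, pre-Cre clones 53 and 92), 42MGBA corrected (53-1, 53-7, 92-6), HCT116 wild-type (24, 27) and HCT116 knockout (7, 21). The arrays of a line correlated with each other at r of 0.986 or more over all rows, and no pair held identical values. Principal components were computed within each line on the tested genes, centred on the line's mean. The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, except those named as chosen later.

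Of the rows, 19460 had 1 gene symbol in the platform annotation, 1754 had several and 12083 were not listed there. Symbols were updated through the Entrez identifier to RefSeq names of assembly GRCh38.p14 for 19429 of the 19460 rows, and 31 kept the older symbol. Only rows with 1 gene were tested. They stood for 18417 genes, 769 of them with several rows, and the row with the highest mean over the 16 arrays represented the gene. Among the rows, 557 repeated the values of another, 407 of them with a listed gene. A gene was tested if its row lay above the median of all rows of an array on at least 2 arrays, which left 12978 genes, 12955 with a chromosome. The chromosome and the order of neighbouring genes came from the same RefSeq table.

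Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on the deposited log2 values, with all 16 arrays in 1 fit of 6 groups that share 1 estimate of the spread per gene. Each SE and p-value rests on this shared spread. For a gene that varied more in 1 line than in the others they understate the spread within that line. The contrasts were deficient minus proficient in each line, the mean of the 3 lines and the differences between lines. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes of a contrast, with a threshold of 0.05. STAG2 was named first. For each line and for the mean, the named genes were the 10 largest rises and the 10 largest falls among genes past the threshold whose deficient and proficient arrays did not overlap. Where under 5 qualified in a direction, the list was filled to 5 by the smallest p. For each difference between lines the 3 genes with the smallest p were named, for each gene list up to 4 members with the smallest p, and up to 10 genes that passed in more than 1 line. STAG1 in HCT116 was added to its values in the other lines, where the rule names it.

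The 28 gene lists, written from textbook knowledge, were cohesin subunits and regulators, condensin and SMC5/6 complex, kinetochore and spindle checkpoint, G1/S and DNA replication, G2/M and mitosis, p53 target genes, homologous recombination and Fanconi genes, interferon-stimulated genes, NF-kB and inflammatory genes, MHC class I presentation, immediate early and AP-1 genes, hypoxia and glycolysis, unfolded protein and amino acid response, cholesterol biosynthesis, extracellular matrix and mesenchymal genes, Wnt/beta-catenin target genes, Notch pathway genes, HOX genes, the beta protocadherin cluster, imprinted genes, cancer-testis genes, genes near STAG2, ribosome biogenesis and MYC targets, cytosolic ribosomal proteins, oxidative phosphorylation, heat shock genes, neural and glial genes, and colorectal epithelial genes. They were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and 23 chromosomes in the same way. With an estimated correlation no list or chromosome passed in any comparison (0 by camera); at an unadjusted p under 0.05 there were 1 list in H4, 2 in 42MGBA, 1 in HCT116 and 0 in the mean, and 3 chromosomes in H4. fry, which asks whether a list's genes move on balance one way without comparing them with other genes, also gave 0 lists, with 4, 2, 1 and 1 at an unadjusted p under 0.05.

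The clone numbers are read here as giving the clone of origin, which the labels do not state. In H4 8-1 and 8-3 then share a parent. In 42MGBA 53 pairs with 53-1 and 53-7 and 92 with 92-6. The deviations of these pairs from their group means correlated at 0.05, 0.16 and -0.17. A fit with the parent clone as a replicate block is given beside results that it changes, and the parental array then adds nothing to the comparison. The other alternatives were a separate fit of each line, no filter and a stricter filter above percentile 75, the mean of all rows of a gene, quantile normalization over the 16 arrays, arrays centred on their median, trended and robust eBayes, array weights, the parent clone as a random block, corrected clones of 1 parent averaged, the parental arrays left out, thresholds of 0.01 and 0.10, a minimum of 1.5-fold, each array left out in turn, and, added after seeing the data, the 42MGBA arrays left out and the replicate block with camera's estimated correlation.

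The steps were tested on simulated arrays for the 12978 genes with known changes in 200 genes per comparison. H4, the mean and the difference between H4 and 42MGBA held further changed genes. At log2 differences of 0.5, 1 and 2 the share recovered was 74.6%, 97.0% and 100% in H4, 50.7%, 98.5% and 100% in 42MGBA, 40.3%, 92.5% and 100% in HCT116, 91.0%, 100% and 100% in the mean of the lines, and 23.9%, 92.5% and 100% in the difference between H4 and 42MGBA. Unchanged genes made up 34 of 740 calls in H4, 7 of 173 in 42MGBA, 7 of 162 in HCT116, 21 of 387 in the mean and 15 of 283 in the difference. A shifted list and a shifted chromosome simulated in H4 were both recovered. By camera 1 of 27 other lists and 0 of 22 other chromosomes were past the threshold. Members of other lists on the shifted chromosome were shifted with it, so that 1 list need not be a false call. The simulated noise was independent between genes and arrays, with 1 spread per gene in all lines. It held no correlation within lists and no clone structure, whereas the ribosome biogenesis list had an estimated correlation of 0.71. In the real H4 arrays other splits gave up to 13 lists. The simulated rates therefore do not carry over to the real arrays. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.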

Results

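Gene expression was measured in 16 cultures of 3 established human cancer cell lines that differed in STAG2, the X-linked gene for a subunit of cohesin, the ring complex that holds sister chromatids together. H4 and 42MGBA are brain tumour lines that carry a STAG2 mutation, and HCT116 is a colorectal carcinoma line with an intact gene. In H4, the parental line and the non-recombinant clones 10 and 12 were STAG2-deficient, and the knock-in clones 8-1, 8-3 and 88-1 had a corrected gene. In 42MGBA, the parental line and clones 53 and 92, which carry the knock-in before Cre recombination, were labelled deficient, and the post-Cre clones 53-1, 53-7 and 92-6 were labelled corrected. In HCT116, the non-recombinant clones 24 and 27 were wild-type and clones 7 and 21 were STAG2 knockouts. Each array came from a growing, subconfluent culture, and 12978 genes were tested. The number of arrays, 3 against 3 in H4 and 42MGBA and 2 against 2 in HCT116, limits the precision. Differences are deficient minus proficient on the log2 scale, and p-values measure only the spread between these clones, which include differences between clones that have no link to STAG2.

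STAG2 itself was examined in every array. In H4 its level was 6.72 ± 0.21 (SD, n = 3) in deficient and 8.91 ± 0.04 (SD, n = 3) in corrected arrays, 4.57-fold lower in the deficient cells. In HCT116 it was 6.85 ± 0.41 (SD, n = 2) in the knockouts and 9.29 ± 0.01 (SD, n = 2) in the wild-type clones, 5.41-fold lower in the knockouts. In 42MGBA the arrays labelled corrected did not have a raised STAG2 level, with 5.53 ± 0.12 (SD, n = 3) against 5.23 ± 0.44 (SD, n = 3) in the deficient arrays. The log2 difference was -2.19 in H4 (95% interval -2.59 to -1.79, adjusted p = 2.37e-05), -2.44 in HCT116 (-2.92 to -1.95, adjusted p = 0.000115) and -0.30 in 42MGBA (-0.70 to 0.10, adjusted p = 1.00). When each line was fitted alone, the adjusted p in HCT116 was 0.0616, the highest of its alternatives, whose lowest was 2.77e-05 without the parental arrays.

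The 42MGBA values lie on another scale than those of the other lines, with array medians of at most 5.05 against at least 6.23 in H4 and 6.24 in HCT116, so levels were also compared as ranks within an array. STAG2 stood on average at percentile 84.1 of the rows in corrected H4 arrays and at 87.3 in wild-type HCT116 arrays. In deficient arrays it stood at 56.9 in H4 and 58.8 in HCT116. The 42MGBA arrays stood at 53.5 when labelled deficient and at 57.9 when labelled corrected, which is where the deficient arrays of the other lines lie. The 42MGBA parental array had the lowest value, 4.75, and clone 92, labelled deficient, had 5.60, above 2 of the 3 arrays labelled corrected. STAG2 therefore does not check the labels of this line, and directions within 42MGBA rest on the labels alone. STAG1, which encodes the alternative subunit at the same position of cohesin, differed by 0.27 (SE 0.12) in H4, 0.21 (SE 0.12) in 42MGBA and 0.12 (SE 0.15) in HCT116, in no line past the threshold (adjusted p = 0.276, 1.00 and 0.898).

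**Figure D1:**
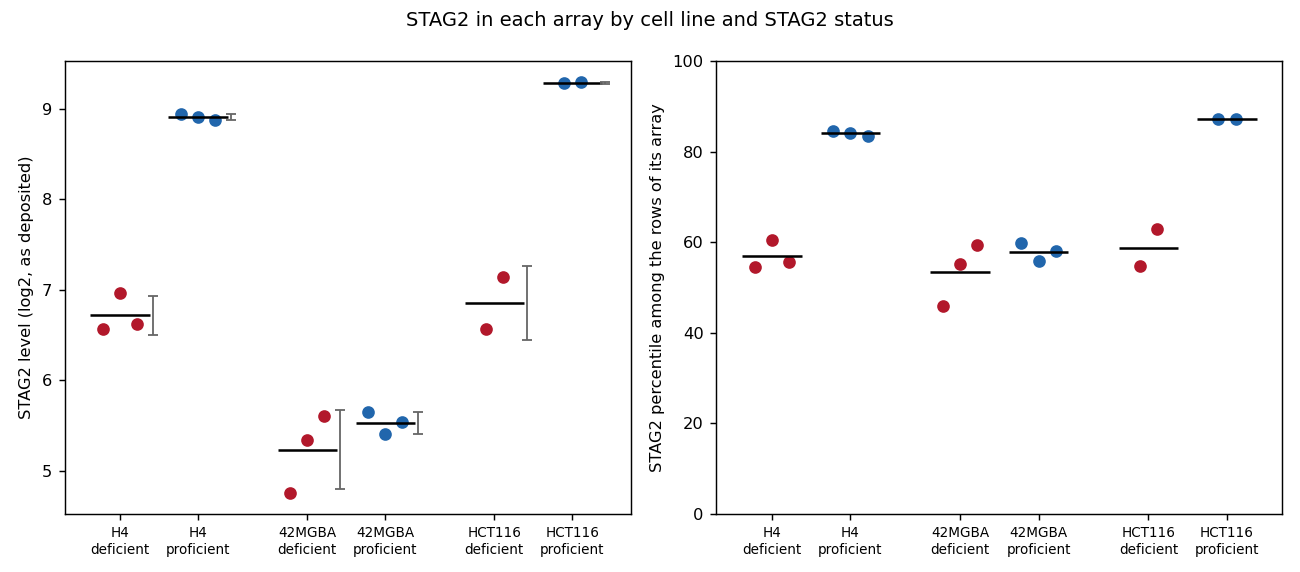
STAG2 in each of the 16 arrays by cell line and STAG2 status, as the log2 value (left) and as the percentile of STAG2 among all rows of its array (right). Points are arrays, black lines are group means and grey bars are 1 SD; corrected H4 and wild-type HCT116 arrays lie near 9 on the log2 axis, and all 6 arrays of 42MGBA lie between 4.75 and 5.65.

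The comparison of deficient with corrected H4 cells asked which genes change with STAG2 in a glioma line. MMP3, which encodes the matrix protease stromelysin, was 13.2-fold higher in the deficient cells, at 10.27 ± 0.64 (SD, n = 3) against 6.55 ± 0.55 (SD, n = 3). ST8SIA4, a sialyltransferase that makes polysialic acid, was 8.27-fold higher. FRMD4B, a FERM-domain scaffold protein, was 6.32-fold lower, at 5.57 ± 0.31 (SD, n = 3) against 8.23 ± 0.26 (SD, n = 3). FAP, a surface protease of activated fibroblasts, was 6.08-fold lower. In all, 429 genes changed, 169 higher and 260 lower in the deficient cells, and 250 of them by at least 1.5-fold.

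The further genes with the largest rises in deficient H4 cells were the drug and bilirubin transporter ABCC2 (2.98, SE 0.57), the olfactory receptor gene OR51B4 (2.47, SE 0.46), RGS18, a regulator of G-protein signalling (2.45, SE 0.25), the microsomal cytochrome CYB5A (2.30, SE 0.17) and the secreted metalloprotease ADAMTS19 (2.16, SE 0.30). PTGS2, the inducible cyclooxygenase, rose by 1.97 (SE 0.32), the cadherin CDH7 by 1.87 (SE 0.23) and TXNIP, the thioredoxin-binding protein, by 1.82 (SE 0.34). Among the largest falls were TAC1, the precursor of substance P (-2.59, SE 0.39), the matrix proteoglycan decorin, DCN (-2.48, SE 0.46), the kinase DAPK1 (-2.45, SE 0.32), the enamel matrix gene AMTN (-2.29, SE 0.37) and COL3A1, the chain of type III collagen (-2.24, SE 0.47). GABRQ, a subunit of the GABA-A receptor (-2.22, SE 0.36), and P3H2, a collagen prolyl hydroxylase (-2.20, SE 0.29), were also among them. In deficient arrays TAC1 (4.06 ± 0.34, SD, n = 3) and DCN (4.27 ± 0.28, SD, n = 3) lay under the arrays' lower quartile of at least 4.49, where a signal was not shown to exceed background, so the size of these falls is uncertain. In the deficient group ABCC2 varied more than the other named genes, with an SD of 1.84 (n = 3). The SEs use the spread shared over the lines, and in 42MGBA ABCC2 had SDs of 0.02 in deficient and 0.08 in corrected arrays (n = 3 each). The SE of 0.57 therefore understates the spread of ABCC2 in H4. Without 1 array its difference ran from 1.97 (without clone 10) to 3.79, and that of OR51B4 from 1.72 to 3.19, of TAC1 from -3.13 to -1.96 and of COL3A1 from -2.97 to -1.64.

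Of the 429 genes, 426 had deficient arrays that did not overlap the corrected arrays. Over all genes tested 20.8% did so, and chance gives 10% for 3 arrays against 3. The count ranged from 169 without clone 8-3 to 631 without the parental array, and was 195 without clone 12, 223 without 8-1, 231 without 88-1 and 282 without clone 10. Clone 10 stood apart in this line, with a first principal component of -30.2 against -0.76 and -12.5 in the other deficient arrays. The count was 165 with corrected clones that share a parent clone averaged, which are 8-1 and 8-3 in this line. That fit also averaged such clones in another line, from which the shared spread is partly taken. The lower count can therefore not be credited to 8-1 and 8-3 alone. With the spread taken from the H4 arrays alone, 34 genes passed, 32 of them among the 429. Of the 20 genes with the largest changes, all but COL3A1 passed without any 1 of the 6 arrays; COL3A1 passed in 3 of the 6 fits, with the highest adjusted p, 0.0736, without 8-1.

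Extracellular matrix and mesenchymal genes were the list with the clearest shift in H4. Of its 34 measured members 31 were lower in deficient cells, with a mean difference of -0.41. COL4A1 (-1.34, SE 0.21) and COL4A2 (-0.96, SE 0.17), the chains of basement membrane collagen, COL1A1 (-1.49, SE 0.27), a chain of the main fibrillar collagen, and COL6A3 (-0.53, SE 0.10) fell. Over all genes tested 7 members fell and 1 rose, and adjusted over the list alone 10 fell and 2 rose. The shift of the list passed camera's test with the preset correlation (adjusted p = 7.31e-06) in all 6 fits without 1 array. The adjusted p was 0.460 with an estimated correlation.

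Cholesterol biosynthesis genes were lower in deficient H4 cells, 15 of 18 with a mean difference of -0.35 (adjusted p = 4.31e-05, and adjusted p = 0.799 with an estimated correlation). SC5D, a sterol desaturase of the late pathway, fell by 0.88, and adjusted over the list alone FDPS (-0.53), SQLE (-0.79), the squalene epoxidase, and NSDHL (-0.39) passed as well. Hypoxia and glycolysis genes were higher, 21 of 26 with a mean difference of 0.29 (adjusted p = 0.00155, and adjusted p = 0.799 with an estimated correlation). HK2, a hexokinase of the first glycolytic step, rose by 1.14 and PFKFB3, a regulator of glycolysis, fell by 0.50. Adjusted over the list alone 4 members rose and 1 fell, among them P4HA2 (0.63), a collagen prolyl hydroxylase, and TPI1 (0.31), triosephosphate isomerase.

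Lists of proliferation and repair genes were lower in deficient H4 cells by small amounts. The mean difference was -0.17 for G1/S and DNA replication (29 of 31 lower, adjusted p = 0.00312), -0.14 for kinetochore and spindle checkpoint genes (22 of 29, adjusted p = 0.00582), -0.17 for homologous recombination and Fanconi genes (16 of 19, adjusted p = 0.00586) and -0.14 for G2/M and mitosis (25 of 30, adjusted p = 0.00670). Each had an adjusted p = 0.799 with an estimated correlation. No member of these lists passed over all genes or adjusted over the list alone; the helicase gene BRIP1 (-0.44, adjusted p = 0.0908) came nearest. Without clone 10 these 4 lists no longer passed (adjusted p = 0.713, 0.580, 0.209 and 0.751 in the order given), nor did hypoxia and glycolysis (0.217). Without 8-1 the G1/S (0.253), kinetochore (0.336) and G2/M lists (0.544) did not pass, and without 88-1 the homologous recombination list did not (0.106).

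Genes of chromosome 7 were higher as a group in deficient H4 cells. Of its 596 tested genes 77.3% had a positive difference, against 54.4% of all genes, and the mean difference was 0.13 (adjusted p = 1.35e-07). On chromosome 7 40 genes rose and 9 fell. Chromosome 18 shifted the other way, with a mean of -0.08 over 187 genes (adjusted p = 0.0153). For each of these chromosomes the adjusted p was 0.0733 with an estimated correlation. Chromosome 7 passed in all 6 fits without 1 H4 array (adjusted p from 1.30e-08 to 7.19e-05), whereas chromosome 18 did not pass without the parental array (0.0770) or clone 12 (0.0731). In most other splits of the 6 H4 arrays chromosome 7 passed camera's test with the preset correlation too (adjusted p from 0.00146 to 0.0472 where it passed). Chromosome 18 passed with the parental array, clone 12 and 8-3 set against the rest (adjusted p = 0.0249, mean -0.04). The mean of chromosome 7 was at most 0.07 in size in the other splits, against 0.13 in the real grouping.

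**Figure D2:**
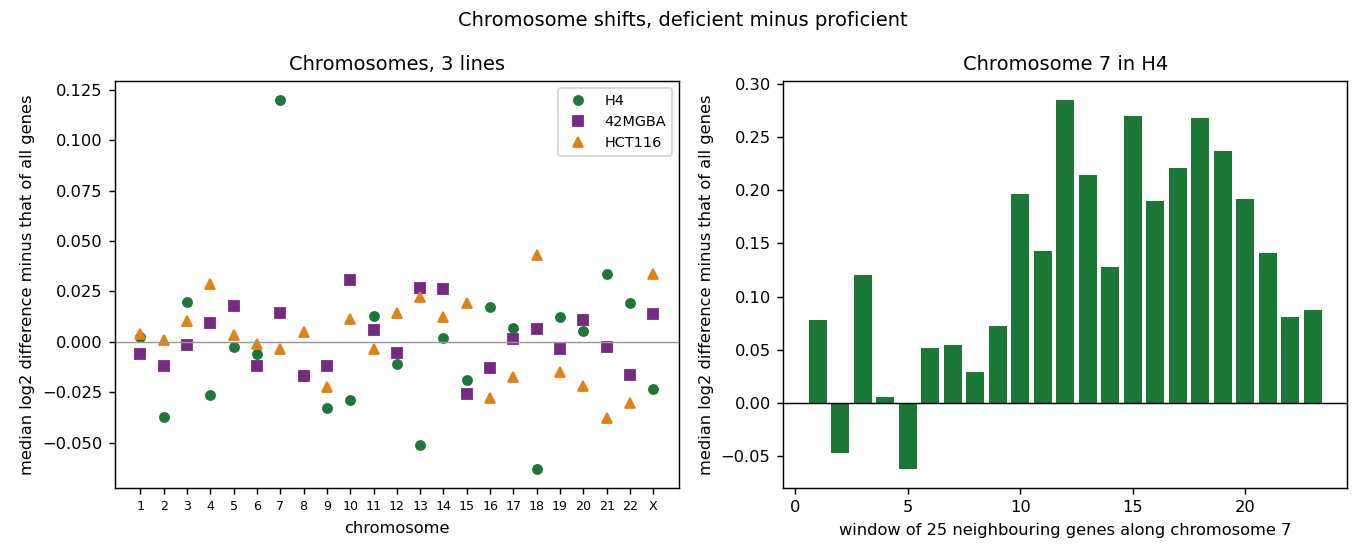
Left, median log2 difference of each chromosome's genes minus that of all genes in the 3 lines; right, the same quantity in H4 for windows of 25 neighbouring genes along chromosome 7. Chromosome 7 in H4 lies at 0.12, and 21 of its 23 windows lie above 0.

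In 42MGBA the arrays labelled deficient and corrected were compared in the same way, with the reservation on STAG2 given above. No gene passed (0 of 12978 by limma, lowest adjusted p = 1.00); 512 genes had an unadjusted p under 0.05, where 648.9 are expected by chance. The largest differences among the genes with the smallest p were lower values of ITGA6, a laminin-binding integrin subunit (-1.52, SE 0.29), KITLG, the ligand of the receptor KIT (-1.04, SE 0.22), and TNFRSF21, a death-domain receptor (-0.99, SE 0.23). MALT1, a paracaspase of NF-kB signalling (-0.54, SE 0.13), and the RNA helicase DDX19A (-0.36, SE 0.08) had smaller differences; a further row of DDX19A differed by -0.09. On the higher side were TSHZ1, a zinc-finger transcription factor (0.70, SE 0.17), the spliceosomal RNA RNU5A-1 (0.62, SE 0.15), the smooth muscle actin ACTG2 (0.55, SE 0.14), DTWD2 (0.48, SE 0.11) and the endosomal syntaxin STX7 (0.38, SE 0.09). None of these 10 genes passed (adjusted p = 1.00 for each).

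With the parent clone as a block, which compares 53 with 53-1 and 53-7 and 92 with 92-6, 0 genes passed by limma and 1032 had an unadjusted p under 0.05; STAG2 differed by -0.08 (adjusted p = 0.923). Without 53-1 9 genes passed and without clone 92 2 did, ITGA6 being past the threshold in 2 of the 6 fits without 1 array and ACTG2 in 1.

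Of 28 gene lists 5 shifted in 42MGBA, although no member of any list passed over all genes tested. Genes of the unfolded protein and amino acid response were lower in arrays labelled deficient, 21 of 25 with a mean of -0.30 (adjusted p = 2.34e-09), among them the serine pathway genes PSAT1 (-0.77, SE 0.21), PHGDH (-0.58, SE 0.19) and SHMT2 (-0.45, SE 0.14) and the stress gene CHAC1 (-0.56, SE 0.18). The neural adhesion genes of the beta protocadherin cluster were higher, 12 of 12 with a mean of 0.36 (adjusted p = 2.72e-09), such as PCDHB5 (0.55, SE 0.25) and PCDHB11 (0.32, SE 0.14). For both lists the adjusted p was 0.540 with an estimated correlation. Adjusted over the list alone 0 of their members passed by limma.

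Cholesterol biosynthesis genes (16 of 18 lower, mean -0.24, adjusted p = 0.00200), interferon-stimulated genes (21 of 29 higher, mean 0.13, adjusted p = 0.00873) and G1/S genes (26 of 31 lower, mean -0.12, adjusted p = 0.0368) also shifted. For these 3 lists the adjusted p was 0.864 with an estimated correlation, and adjusted over the list alone 0 members passed by limma. In this group HMGCS1, the synthase at the entry of the mevalonate pathway, differed by -0.64 (SE 0.33) and SAMD9, an antiviral factor, by 0.49 (SE 0.26). Without clone 53 none of the 3 passed (adjusted p = 0.307, 0.555 and 0.853), and the interferon list then had the opposite direction. The interferon list did not pass without 92-6 (0.253) either, nor did the G1/S list without 92 (0.120), 53-7 (0.0860) or 92-6 (0.437).

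With the parent clone as a block, 10 lists shifted in 42MGBA in place of 5. Higher in arrays labelled deficient were the interferon-stimulated genes (adjusted p = 1.30e-16) and the beta protocadherins (2.15e-10), and the unfolded protein response (2.11e-09), G1/S (3.88e-08), G2/M (1.29e-06), cholesterol (4.67e-06), ribosome biogenesis (2.02e-05) and kinetochore lists (0.000100) were lower. Extracellular matrix and HOX genes were higher (0.0307 for both). With this block 0 lists passed by camera with an estimated correlation, and 0 had an unadjusted p under 0.05; the adjusted p = 0.623 with an estimated correlation for ribosome biogenesis, and for the other 9 lists adjusted p = 0.596 with an estimated correlation. No chromosome passed without the block (0 of 23 by camera, 4 at an unadjusted p under 0.05), with chromosome 10 nearest (adjusted p = 0.0501), where only 92-6 stood apart (median deviation -0.13 against -0.02 to 0.03 in the other 5 arrays), and 4 passed with it, of which 0 did with an estimated correlation (1 at an unadjusted p under 0.05).

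The comparison of HCT116 knockout with wild-type clones asked what loss of STAG2 changes in a line that had an intact gene. ANGPT2, which encodes an angiopoietin that acts on blood vessels, was 8.37-fold higher in the knockouts, at 7.87 ± 0.09 (SD, n = 2) against 4.81 ± 0.20 (SD, n = 2). ITGB8, an integrin subunit that binds latent TGF-beta, was 5.73-fold higher at 7.74 ± 0.07 (SD, n = 2) against 5.22 ± 0.19 (SD, n = 2). Besides STAG2, the largest fall was in ADGRF1, an adhesion G-protein-coupled receptor, which was 3.18-fold lower. In all, 17 genes changed, 10 higher and 7 lower in the knockouts.

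The other genes that rose were TM4SF18, a small transmembrane protein (2.11, SE 0.17), the Polycomb-related gene SCML1 (1.71, SE 0.26), GALNT3, which starts mucin-type glycosylation (1.14, SE 0.18), SMIM14 (1.11, SE 0.20), the nuclear receptor NR4A2 (1.09, SE 0.17), the actin-binding nebulette gene NEBL (0.86, SE 0.12), the Rab effector EXPH5 (0.79, SE 0.13) and FXYD3, a regulator of the sodium pump (0.79, SE 0.12). The others that fell were the carbonic anhydrase CA2 (-0.89, SE 0.16), ITGB4, the integrin subunit of hemidesmosomes (-0.86, SE 0.12), the lipoic acid synthase LIAS (-0.68, SE 0.12), the cytidine deaminase CDA (-0.67, SE 0.12) and PABIR2 (-0.58, SE 0.11).

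The groups did not overlap for any of the 17 genes, as for 40.7% of all genes tested. STAG2, ANGPT2 and TM4SF18 passed in all 4 fits without 1 HCT116 array, with a highest adjusted p of 0.00331, 7.87e-06 and 0.00159, and each of the other 14 lost its call in at least 1 of them. The count was 5 without clone 27, 77 without clone 7 and 47 without clone 21. Clone 21 stood apart in this line, with a first principal component of 23.6 against -9.14 to -6.61 in the other arrays. With the spread taken from the HCT116 arrays alone, 3 genes passed, all among the 17.

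**Figure D3:**
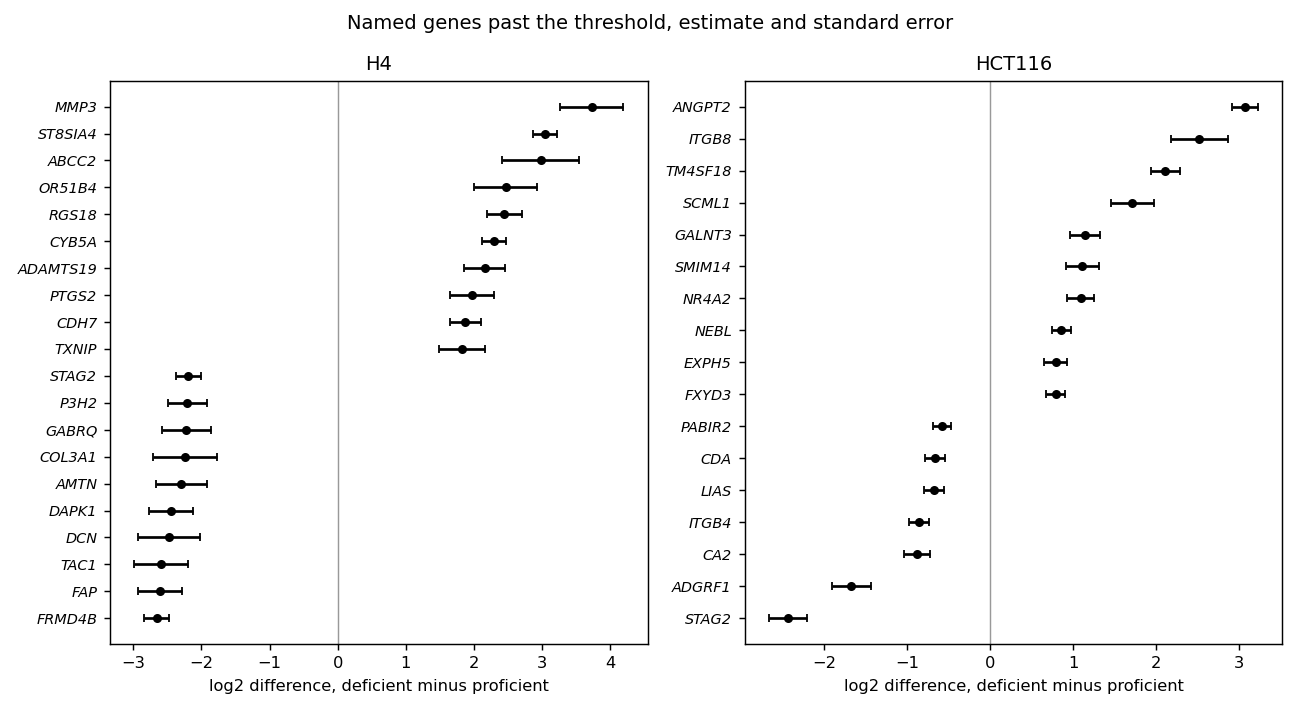
Log2 difference, deficient minus proficient, of the named genes that passed the threshold in H4 (left, 3 against 3 arrays) and HCT116 (right, 2 against 2 arrays). Points are estimates and bars are 1 standard error; the values run from -2.66 for FRMD4B to 3.73 for MMP3 in H4 and from -2.44 for STAG2 to 3.06 for ANGPT2 in HCT116.

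G1/S and DNA replication genes were lower in the HCT116 knockouts in 31 of 31 members, with a mean of -0.31 (adjusted p = 1.69e-07), such as the phosphatase CDC25A (-0.58, SE 0.21) and the replication factors MCM10 (-0.56, SE 0.21) and CDC45 (-0.48, SE 0.19). Ribosome biogenesis genes and MYC targets were lower in 25 of 26 (mean -0.30, adjusted p = 3.07e-07), such as NOLC1 (-0.51, SE 0.16). Homologous recombination and Fanconi genes were lower in 16 of 19 (mean -0.19, adjusted p = 0.00890), such as EXO1 (-0.47, SE 0.17). For these 3 lists the adjusted p was 0.893 with an estimated correlation. By limma 0 of their members passed over all genes tested or adjusted over the list alone.

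Immediate early and AP-1 genes were higher in 20 of 25 (mean 0.23, adjusted p = 0.00208, and adjusted p = 0.359 with an estimated correlation). NR4A2 rose, and adjusted over the list alone EGR1 (1.27, SE 0.35), a growth-factor-induced transcription factor, passed as well. G2/M and mitosis genes were higher in 29 of 30 (mean 0.15, adjusted p = 0.00214), among them TOP2A (0.38, SE 0.16), the DNA topoisomerase of mitosis. Cholesterol biosynthesis genes were higher in 14 of 18 (mean 0.18, adjusted p = 0.0172) and p53 target genes in 18 of 25 (mean 0.16, adjusted p = 0.0172). For these last 3 lists the adjusted p was 0.893 with an estimated correlation. Adjusted over the list alone SREBF2 (0.58, SE 0.14), the regulator of sterol synthesis, and the p53 target TP53I3 (0.61, SE 0.15) passed, and no G2/M gene did.

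The G1/S list passed in all 4 fits without 1 HCT116 array. Without clone 7 the immediate early (adjusted p = 0.182), homologous recombination (0.125), cholesterol (0.879) and p53 lists (0.761) did not pass, and without clone 21 the G2/M and ribosome biogenesis lists did not (0.243 for both). The homologous recombination (0.0689) and cholesterol lists (0.315) did not pass without clone 24, nor the p53 list without clone 27 (0.278). No chromosome shifted in HCT116 (0 of 23 by camera, and 0 at an unadjusted p under 0.05).

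**Figure D4:**
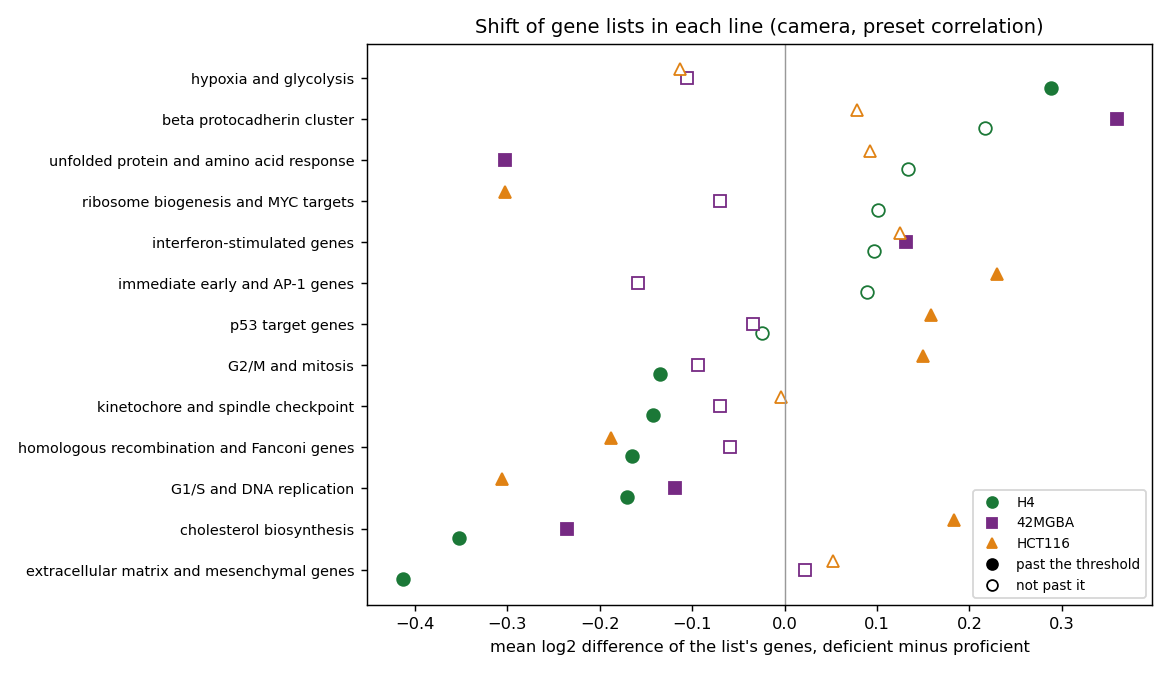
Mean log2 difference, deficient minus proficient, of the 13 gene lists that passed camera's test with the preset correlation in at least 1 line; circles are H4, squares 42MGBA and triangles HCT116. Filled symbols passed and open ones did not; the G1/S list lies at -0.17, -0.12 and -0.31, filled in each line.

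A mean of the differences in the 3 lines was tested, with the reservation on STAG2 in 42MGBA given above. STAG2 had the largest fall (-1.64, SE 0.12, adjusted p = 7.92e-06). GREB1L, a gene needed for kidney and inner ear development, fell by 0.49 (SE 0.08, adjusted p = 0.0258), with -0.48 in H4, -0.24 in 42MGBA and -0.74 in HCT116. Its 42MGBA levels, 2.76 and 3.00, lay under the arrays' lower quartile of at least 3.38, so a change in that line is not shown. In all, 18 genes changed in the mean, 6 higher and 12 lower. The death-domain receptor TNFRSF21 (-0.92, SE 0.15) fell, with -1.66 in H4 and -0.99 in 42MGBA but -0.12 in HCT116, as did PSD3, an exchange factor for ARF GTPases (-0.47, SE 0.07). DOCK11 was also among the named falls, with a mean difference of -0.61 to -0.51 over the fits without 1 array.

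The rises in the mean came mainly from a single line. ST8SIA4 (1.12, SE 0.11), CYB5A (0.75, SE 0.11) and the cytokine IL18 (0.59, SE 0.09) owed them to H4, and ANGPT2 (1.00, SE 0.08) to HCT116. NR4A2 (0.50, SE 0.08) had 0.50 in H4, -0.08 in 42MGBA and 1.09 in HCT116. STAG2, ANGPT2 and ST8SIA4 passed in all 16 fits without 1 array, CYB5A in 14, TNFRSF21 in 12, IL18 and PSD3 in 10 each, GREB1L in 8 and NR4A2 in 5. Without HCT116 clone 27 the adjusted p of NR4A2 was 0.160 and that of GREB1L 0.0843, the highest for each. In 42MGBA IL18 (2.16 in deficient and 2.30 in corrected arrays) and ST8SIA4 lay under the lower quartile of at least 3.38. The count was 3 without 42MGBA clone 53 or without HCT116 clone 27, and lay under 12 without any 1 of the 42MGBA arrays other than 53-1 or without HCT116 clone 24. It was 33 without HCT116 clone 7, 57 without clone 21 and 61 without the H4 parental array.

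Among the lists, G1/S and DNA replication genes were lower in the mean in 31 of 31 members (mean -0.20, adjusted p = 3.87e-10, and adjusted p = 0.910 with an estimated correlation). The beta protocadherins were higher in 12 of 12 (mean 0.22, adjusted p = 0.000105) and homologous recombination genes lower in 17 of 19 (mean -0.14, adjusted p = 0.000112). For both the adjusted p was 0.872 with an estimated correlation. These 3 lists passed in all 16 fits without 1 array. Over all genes tested 0 of their members passed by limma, and adjusted over the list alone PCDHB11 (0.35, SE 0.08) and PCDHB9 (0.42, SE 0.14) did.

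Interferon-stimulated genes were higher in the mean in 23 of 29 (mean 0.12, adjusted p = 0.00556), ribosome biogenesis genes lower in 21 of 26 (mean -0.09, adjusted p = 0.00842) and cholesterol genes lower in 16 of 18 (mean -0.13, adjusted p = 0.0203). In H4, 42MGBA and HCT116 the means were 0.10, 0.13 and 0.13 for interferon-stimulated genes. They were 0.10, -0.07 and -0.30 for ribosome biogenesis and -0.35, -0.24 and 0.18 for cholesterol genes, so the last 2 lists differed in sign between lines. For these 3 lists the adjusted p was 0.983 with an estimated correlation, and 0 of their members passed by limma over all genes or adjusted over the list alone. They passed in 12, 10 and 9 of the 16 fits without 1 array, with the highest adjusted p of 0.261 without H4 clone 10, 0.720 without HCT116 clone 21 and 0.361 without HCT116 clone 21.

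STAG2 was the only gene that changed in the same direction in more than 1 line by the tests within lines. The 260 genes that fell in H4 and the 7 that fell in HCT116 shared only STAG2, where 0.140 are expected for independent lists. STAG2 was altered by design in both lines, so this overlap was fixed in advance and shows no common response. The 169 and 10 that rose shared none, where 0.130 are expected. Across genes, which are not independent replicates, the differences correlated with a Pearson r of 0.03 between H4 and 42MGBA, -0.05 between H4 and HCT116 and 0.08 between 42MGBA and HCT116, with Spearman correlations of 0.00, -0.07 and 0.10. Regroupings of the arrays within the lines gave a correlation as large in 71 of 100, 20 of 30 and 12 of 30 cases, the real grouping included.

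Whether a gene's difference itself differed between lines was tested as a difference of differences. The STAG2 fall was larger in H4 than in 42MGBA by -1.89 (SE 0.26, adjusted p = 0.00902), and larger in HCT116 than in 42MGBA by 2.14 (SE 0.29, adjusted p = 0.0140); between H4 and HCT116 the difference did not pass (0.24, 95% interval -0.39 to 0.87, adjusted p = 0.777). The difference between 42MGBA and HCT116 lost its call in 4 of 10 fits without 1 array, with the highest adjusted p, 0.0820, without HCT116 clone 27. Between H4 and 42MGBA 33 genes differed, led by ST8SIA4 (3.10, SE 0.25), FRMD4B (-2.83, SE 0.25) and CYB5A (2.31, SE 0.24). Between H4 and HCT116 38 genes differed, led by ANGPT2 (-3.14, SE 0.21), FRMD4B (-3.38, SE 0.28) and TM4SF18 (-2.48, SE 0.22). Between 42MGBA and HCT116 the 3 genes were ANGPT2 (-3.07, SE 0.21), TM4SF18 (-2.28, SE 0.22) and STAG2. In 42MGBA ST8SIA4 (2.51 in deficient and 2.57 in corrected arrays), FRMD4B (2.79 and 2.62) and TM4SF18 (2.68 and 2.86) lay under the lower quartile of at least 3.38. In deficient H4 arrays TM4SF18 (4.22) lay under that of at least 4.49, so the size of its difference between H4 and HCT116 is uncertain. ANGPT2 (3.39 in both groups of 42MGBA) lay close to the lower quartile of that line. The differences of ST8SIA4, FRMD4B, TM4SF18 and ANGPT2 from 42MGBA therefore restate the changes in H4 and HCT116. They do not show that 42MGBA responds otherwise. CYB5A lay well above the lower quartile in 42MGBA (8.34 in deficient and 8.35 in corrected arrays), so only the reservation on STAG2 in that line applies to it.

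Leaving out 1 array moved these counts by over 1.5 times. Against 42MGBA, the H4 count was 111 without the H4 parental array, 12 without 42MGBA clone 53, 14 without 92-6, 15 without the 42MGBA parental array, 92 or 53-7, 19 without 8-1 and 21 without 8-3. Against HCT116, it was 140 without HCT116 clone 7, 119 without the H4 parental array, 65 without H4 clone 10, 24 without 8-3, 18 without HCT116 clone 24 and 10 without clone 27. Between 42MGBA and HCT116 the count was 16 without HCT116 clone 7 and 30 without clone 21.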

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

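The test for a label swap within 42MGBA, that of chromosome 7 without each array, and those of clone 10 alone and of chromosome 7 genes among the H4 changes, and the splits for the G1/S and beta protocadherin shifts were chosen only after the result was seen; the other tests of this part were set before.

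STAG2 changed less in 42MGBA than in the other lines, by the test of the difference itself: the H4 minus 42MGBA difference was -1.89 (adjusted p = 0.00902) and the 42MGBA minus HCT116 difference was 2.14 (adjusted p = 0.0140). The low STAG2 level of the arrays labelled corrected is not accounted for by the other scale of the 42MGBA arrays: of 1302 genes ranked like STAG2 in proficient H4 and HCT116 arrays, 3.07% (40 genes) stood as low as STAG2 there. A swap of labels within the line would need an array with a high level, and the highest percentile over its 6 arrays was 59.8. Low output of the region would lower the neighbouring genes, and the 18 neighbours changed in percentile by a median of -4.03 (interquartile range -10.7 to 3.19), against -27.7 for STAG2, with 0 of them as low. Samples exchanged with cultures outside the series, a correction that restores the protein but little transcript, and a lower STAG2 output in this line stay open and untested, so a difference in biology may remain.

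Chromosome 7 was higher as a group in deficient H4 arrays, with a mean of 0.13. A few strongly changed genes do not account for it, since genes that did not pass were also higher, by a median of 0.104. Nor does a single array, since the mean was 0.11 to 0.15 in the fits without 1 array. Chromosome 7 passed in 6 of 6 of these fits, but it also passed in most other splits, so the pass adds little. In those splits its mean was at most 0.07 in size. A gain over at least part of the chromosome may account for the shift. Of its windows of 25 genes 91.3% lay above the median of all genes, against at most 71.0% on any other chromosome. That share meets the limit set for a gain spread over the whole chromosome, but it counts windows however little they lie above. The division was not even: the 371 genes from ASL to DYNC2I1 had a median of 0.18 with 85.7% positive and the 225 from FAM20C to GUSB 0.04 with 63.6%, a boundary chosen after the windows were seen. In the 225 genes the median deviation from the line's mean was 0.01 (parental), 0.05 (clone 10) and -0.02 (clone 12), against -0.03 to -0.02 in the corrected arrays. In the 371 genes the deficient arrays had 0.06 to 0.15 and the corrected arrays -0.11 to -0.08. For clone 12 the shift is thus shown only from ASL to DYNC2I1. Copy number was not measured, and whether the corrected clones lost or the deficient cells gained material, or STAG2 changed the genes' output, stays open.

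The 429 genes changed in H4 were weighed in the same way. Clone 10, which stands apart from the other H4 arrays, does not account for all of them alone, since 53.1% were called without it, nor do chromosome 7 genes, which made up 11.4% and leave 380 without them, 129 higher and 251 lower. Chromosome 7 held 4.59% of the genes tested, so its share of the calls was raised, with 40 of the 169 rises and 9 of the 260 falls. Whether a spread borrowed from the other lines adds calls cannot be told apart from the effect of few arrays: the ratio of the residual SD within H4 to the shared SD had a median of 1.19 (interquartile range 0.880 to 1.44) over the called genes and 0.978 over all genes. Ancestry may also matter, since all 3 corrected arrays come from targeted and selected clones and 8-1 and 8-3, by their numbers, share a parent. Averaging corrected clones of 1 parent gave 165 genes, but that fit also averaged clones of another line that adds to the shared spread. In HCT116, where no arrays were averaged, the same fit gave 10 genes against 17. The 165 therefore does not isolate the effect of shared ancestry in H4. The 10 splits of the 6 arrays are too few for a share under 0.05; the real split gave 429 genes and the highest other 22, with 1 split as large.

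The other splits of the arrays bear on the remaining counts. In H4 7 lists shifted in the real split and up to 13 in others (8 of 10 splits as large), and 2 chromosomes against up to 5 (9 of 10). In 42MGBA 5 lists shifted against up to 10 (8 of 10). There 0 genes changed against up to 7 (10 of 10 as large) and 0 chromosomes against up to 6 (10 of 10). A count of 0 is met by every split, so these 2 results were fixed in advance and tell nothing about the real grouping. With 10 splits a share under 0.05 was out of reach. For the lists in both lines and the chromosomes in H4, most other groupings of the same arrays gave counts as large. These counts therefore do not set the real grouping apart. For the mean of the 3 lines 100 of 1200 splits were drawn. For its 18 genes the highest other was 9, with 1 of 100 as large. The splits regroup all 3 lines at once, so most of them also break up the H4 groups. They can therefore exclude only that no line changed, and only if arrays of clones that share a parent count as independent. A change common to the lines is not shown by them, and STAG2, altered by design, is 1 of the 18. The count was 7 with corrected clones of 1 parent averaged and 3 without 42MGBA clone 53. Chance cannot be excluded for the count of 6 lists in the mean (highest other 11, 56 of 100). The G1/S shift of -0.20 and the beta protocadherin shift of 0.22 were picked out of 28 lists because they passed in the mean, so each was held against the largest shift of any list. Chance cannot be excluded for either (29 and 14 of 100 splits as large, highest other 0.34 in size).

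Differences between lines were found by the tests of the differences for 33 genes between H4 and 42MGBA, 38 between H4 and HCT116 and 3 between 42MGBA and HCT116. Whether chance can be excluded for the first of these stays open: 12 of 100 splits drawn from 200 gave a count as large and the highest other gave 170, but this share does not measure chance alone, since 14 of the 100 kept the real H4 groups and with them the H4 change, and 10 of these were as large. Of the 86 without them 2 were as large, 1 of which gave the 170. What sets these splits apart was not tested. The other 2 counts were not run over splits, since HCT116 has 2 arrays per group. By gene, H4 minus 42MGBA was 3.10 for ST8SIA4, -2.83 for FRMD4B and 2.31 for CYB5A, H4 minus HCT116 was -3.14 for ANGPT2, -3.38 for FRMD4B and -2.48 for TM4SF18, and 42MGBA minus HCT116 was -3.07 for ANGPT2 and -2.28 for TM4SF18.

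Of 28 lists, 6 differed between H4 and 42MGBA. The mean difference of differences was 0.25 for immediate early genes, 0.39 for hypoxia and glycolysis, 0.44 for the unfolded protein response, -0.44 for extracellular matrix genes, 0.16 for oxidative phosphorylation and -0.14 for HOX genes. Between H4 and HCT116 6 differed, -0.29 for G2/M, -0.18 for p53 targets, 0.40 for hypoxia and glycolysis, -0.54 for cholesterol biosynthesis, -0.47 for extracellular matrix genes and 0.40 for ribosome biogenesis. Between 42MGBA and HCT116 8 differed, 0.19 for G1/S, -0.24 for G2/M, -0.19 for p53 targets, -0.39 for immediate early genes, -0.39 for the unfolded protein response, -0.42 for cholesterol biosynthesis, 0.23 for ribosome biogenesis and 0.28 for beta protocadherins. None of these 20 held with an estimated correlation (lowest adjusted p = 0.522, 0.734 and 0.103).

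Of the 13837 rows without a unique gene name 6250 lay above the filter. In H4 23 of them changed, 4 higher and 19 lower. In 42MGBA and HCT116 0 did by limma, with 330 and 319 at an unadjusted p under 0.05.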

How the results depend on the processing

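The settings without the 42MGBA arrays and with the replicate block and an estimated correlation were chosen only after the result was seen; the others were planned. No named gene turned its direction under any setting; of the lists that passed, interferon-stimulated genes in 42MGBA did so without clone 53. Of 734 values of named genes under settings other than leaving out an array, 648 kept their side of the threshold and 86 no longer passed; of 504 without 1 array, 420 kept it, 81 no longer passed and 3 newly passed. Of the 86, 27 came from the separate fit of each line, among 47 values. Limits are the number of arrays, 2 or 3 per group, and the other scale of the 42MGBA arrays. The cause of the changes was not tested, except that a stricter threshold or a minimum fold lowers a count of genes by construction. The parent clone as a random block was not run for lists and chromosomes, since camera takes no block; its consensus correlation was 0.155.

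With a separate fit of each line 34 genes changed in H4, 3 in HCT116 and 0 in more than 1 line by limma (1877 and 993 at an unadjusted p under 0.05 in H4 and HCT116), and STAG2 in HCT116, at -2.44, no longer passed (adjusted p = 0.0616). Without a filter 1 chromosome shifted in H4. With the stricter filter 5 genes changed in HCT116, 21 differed between H4 and HCT116 and 1 between 42MGBA and HCT116, and 1 chromosome shifted in H4 and 2 in 42MGBA. With quantile normalization 10 genes changed in the mean and 16 differed between H4 and HCT116. With arrays centred on their median 2 genes changed in more than 1 line. Trended and robust eBayes gave 11 genes in HCT116. Array weights gave 68 genes differing between H4 and 42MGBA, 65 between H4 and HCT116, 2 genes in more than 1 line, 2 lists in H4 and 1 chromosome in 42MGBA. The split of H4 calls, 169 higher and 260 lower, became 119 and 177 with quantile normalization and 201 and 238 with centring.

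With corrected clones of 1 parent averaged 165 genes changed in H4, 10 in HCT116 and 7 in the mean, 6 differed between H4 and 42MGBA and 13 between H4 and HCT116, and 1 chromosome shifted in 42MGBA. With the parent clone as a replicate block 10 lists and 4 chromosomes shifted in 42MGBA; this block was run for 42MGBA only. With this block and an estimated correlation 0 lists and 0 chromosomes shifted in 42MGBA by camera (0 and 1 at an unadjusted p under 0.05). Without the parental arrays 38 genes changed in the mean, 83 differed between H4 and 42MGBA and 97 between H4 and HCT116, 2 changed in more than 1 line, 11 lists shifted in 42MGBA and 10 in the mean, and 1 chromosome shifted in H4 and 2 in 42MGBA. At a threshold of 0.01 114 genes changed in H4, 7 in HCT116 and 3 in the mean, and 8 differed between H4 and 42MGBA and 8 between H4 and HCT116. At 0.10 the counts were 766 in H4, 29 in the mean, 61 between H4 and 42MGBA and 139 between H4 and HCT116. With at least 1.5-fold 250 changed in H4 and 8 in the mean. With an estimated correlation 0 lists shifted by camera in H4, 42MGBA, HCT116 or the mean and 0 chromosomes in H4, and fry gave 0 lists in each (1, 2, 1 and 0 lists by camera and 4, 2, 1 and 1 by fry at an unadjusted p under 0.05). Without the 42MGBA arrays 190 genes changed in H4 and 3 in HCT116, and 10 differed between H4 and HCT116.

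Without 1 array the counts of genes ran from 169 to 631 in H4, from 0 to 9 in 42MGBA, from 5 to 77 in HCT116, from 3 to 61 in the mean, from 12 to 111 between H4 and 42MGBA, from 10 to 140 between H4 and HCT116, from 2 to 30 between 42MGBA and HCT116, and from 1 to 4 in more than 1 line. Lists ran from 3 to 11 in H4, 3 to 11 in 42MGBA, 3 to 7 in HCT116 and 4 to 8 in the mean, and chromosomes from 1 to 4 in H4, 0 to 4 in 42MGBA and 0 to 0 in HCT116. STAG2 ran from -2.32 to -2.12 in H4, -0.48 to -0.06 in 42MGBA and -2.72 to -2.15 in HCT116. The correlations ran from -0.01 to 0.08 between H4 and 42MGBA, -0.12 to 0.02 between H4 and HCT116 and 0.02 to 0.15 between 42MGBA and HCT116. With 1 array left in an HCT116 group, it is assumed to vary like the others.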

Other observations

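Of the 28 gene lists 13 shifted in at least 1 line and are described in the report; 15 shifted in none. Of the 15, HOX genes shifted in 42MGBA with the parent clone as a block (higher, adjusted p = 0.0307, and adjusted p = 0.596 with an estimated correlation). Single members of these 15 did pass in H4 over all genes tested. Of the oxidative phosphorylation genes UQCRQ (0.45, SE 0.10), NDUFB5 (0.44, SE 0.11) and COX8A (0.38, SE 0.10), subunits of the respiratory chain, rose, and adjusted over the list alone 5 did. Of the NF-kB and inflammatory genes PTGS2 and the cytokine IL11 (0.47, SE 0.09) rose. RNF43 (1.12, SE 0.15), a ubiquitin ligase that dampens Wnt signalling, rose among the Wnt/beta-catenin target genes, and the imprinted gene SGCE (0.48, SE 0.10), which lies on chromosome 7, rose as well. The neural adhesion gene NCAM1 (-1.25, SE 0.32) and the cancer-testis gene PRAME (-0.47, SE 0.11) fell. In lists that shifted in another line but not in H4, the signalling inhibitor SPRY2 (0.94), the antiviral membrane protein BST2 (0.69) and PCDHB11 (0.55) rose. In 42MGBA 3 genes passed only when adjusted over the list alone, the neural cadherin CDH2 (-0.93, SE 0.23) and the actin ACTA2 (0.96, SE 0.25) of the extracellular matrix and mesenchymal genes and the transcription factor ETV4 (-0.51, SE 0.13) of the immediate early genes. In H4 PCDHB7 (0.60), MAGEB2 (0.38), NR4A2 (0.50), PLAGL1 (0.48) and ETS2 (-0.51) did so in their lists, and in the mean of the lines PRAME (-0.26), COL4A1 (-0.51), COL1A1 (-0.60) and COL4A2 (-0.38). In HCT116 the following passed only when adjusted over the list alone: the epithelial cadherin CDH1 (0.68, SE 0.16), the cytokine LIF (-1.26, SE 0.29), the imprinted gene PEG10 (-0.76, SE 0.18), and the Wnt pathway genes BAMBI (1.22, SE 0.30) and RNF43 (-0.66, SE 0.18).

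Without the block, these 15 did not pass by camera with the preset correlation in H4, 42MGBA and HCT116, with adjusted p given in that order. Cohesin subunits and regulators had 0.124, 0.367 and 0.375, condensin and SMC5/6 genes 0.305, 0.592 and 0.543, and genes near STAG2 0.365, 0.770 and 0.674. HOX genes had 0.124, 0.0551 and 0.350, Notch pathway genes 0.584, 0.776 and 0.721, and Wnt/beta-catenin target genes 0.360, 0.426 and 0.736. Oxidative phosphorylation had 0.0753, 0.112 and 0.543, cytosolic ribosomal proteins 0.284, 0.112 and 0.426, and heat shock genes 0.365, 0.705 and 0.709. NF-kB and inflammatory genes had 0.517, 0.198 and 0.709, MHC class I presentation 0.739, 0.146 and 0.709, imprinted genes 0.584, 0.770 and 0.918, and cancer-testis genes 0.709, 0.657 and 0.709. Of the markers of cell identity, neural and glial genes had 0.709, 0.944 and 0.894, and colorectal epithelial genes 0.584, 0.770 and 0.350.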
